A study of Lactobacillus johnsonii with 12 samples.

How the data were processed

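Transcript levels were measured on 12 two-colour oligonucleotide arrays of Lactobacillus johnsonii, a lactic acid bacterium, from a strain that the labels call LA-1. Per the labels, cultures of 400 ml were grown at 37 °C and pH 6.5 with gas sparged at 750 ml/min and stirring at about 200 rpm. Cells from 50 ml were harvested at an optical density of 0.15, and labelled cDNA was made from 5 µg of total RNA. Each array compared 2 RNA samples, 1 labelled with Cy5 (the numerator of the ratio) and 1 with Cy3. The 12 arrays covered 10 RNA samples: 5 conditions in each of 2 numbered series. The conditions were aerobic growth, anaerobic growth with CO2 supplied, and 30, 60 and 120 min after CO2 supply was withdrawn. Of the arrays, 10 formed a closed loop in which every RNA sample was labelled once with each dye, and 2 were shortcuts across it, so that each RNA sample was on 2 or 3 arrays. The labels do not say whether the 2 series came from separate cultures, so p-values measure the spread between these RNA samples, part of which may be technical.

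Per the file headers, each array's deposited file gives for every spot the mean foreground intensity and the mean local background intensity in each dye, with a quality code. These values were neither background-subtracted nor normalized by the authors, and the scanner software is not given in the sources used here. Every file held 43711 spots, of which 43434 carried probes for 1810 gene IDs and 277 were controls, 216 of them for genes foreign to the bacterium. A gene had 9 to 16 probe positions, each spotted as a pair. The deposited value table of the series holds ratios that the authors had normalized. Its columns ran as Cy5 over Cy3 with medians between 0.937 and 1.05, and its log2 values correlated with log2 of the background-subtracted ratios at r = 0.85 to 0.939 over the spots of an array when rows were taken in order. With rows shuffled, the correlations lay between -0.013 and 0.00329. How the authors normalized these ratios stays unknown, and they served as an alternative only.

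The quality code was the same in both dyes. Code 1 marked 2727 spots on the array of aerobic series 2 over CO2-supplemented series 2 and at most 44 spots on any other array. On that array, foreign-gene control spots reached an intensity of 44083 in Cy3, so spots with code 1 were left out. Code 2 marked spots near background and took 26.8% to 56.7% of the gene spots of an array. These were kept. The meaning of the codes is read from the values, since the sources used here do not state it.

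Background was corrected with normexp and an offset of 50 in limma 3.58.1 (R 4.3.3; files were read with the data.table package, version 1.17.8), and log ratios were normalized by loess within each array, with controls at weight 0. Log2 ratios were averaged over the spots of a gene. For each gene, least squares over the 12 arrays then gave 1 relative log2 level for each of the 10 RNA samples and a dye effect of the gene (SD 0.05 over genes). The residual SD was 0.0824. Turning the sign of any 1 array raised it to at least 0.108, which checks the labelled directions of the arrays against each other. A reversal of all 12 arrays would leave the residual SD unchanged, so the common direction rests on the labels. The 10 levels were fitted by condition with limma's lmFit and eBayes (5 residual and 3.46 prior degrees of freedom), so that all conditions share 1 estimate of spread, and p-values were adjusted over 1810 genes by the Benjamini-Hochberg method, with a threshold of 0.05. Errors given as ± are limma's standard errors, and n is 2 RNA samples per condition. A gene counted as above background in a channel when its median spot exceeded the 95th percentile of the foreign-gene spots.

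Data were simulated with 1 pooled spread for all RNA samples of a gene. On them the fit found 57% of genes changed by 0.5 and 95% of genes changed by 1 (log2) in the aerobic comparison. The corresponding shares were 67% and 98% at 30 min, 67% and 94% at 60 min, and 49% and 93% at 120 min. Between 0.373% and 0.87% of unchanged genes were called. The simulation kept neither the larger spread of the CO2-supplemented pair nor errors common to a series. These shares may therefore not hold for the real comparisons. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).

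Gene names could not be given. The reference table pairs names with 1878 genes of another strain of the species (strain NCK2677, assembly ASM1405868v1), and 0 of the 1810 array IDs matched an ID in it. For that reason the 22 gene lists fixed before the data were examined, and their set tests, could not be applied. The rule for named genes, also fixed before, took those with the largest changes among genes that passed and changed the same way in both series; with no names, it allowed at most 2 IDs that rose and 2 that fell per comparison. Where none passed, those with the smallest unadjusted p were taken. The IDs LJ0548, LJ0549 and LJ1254 were fixed before, whatever their p. Probe IDs carry a cross-hybridisation number, which is above 1 for 6027 of 21717 probe positions. Its meaning is not stated, and results with number 1 alone were computed as an alternative.

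The 2 series numbers come from the labels, which number duplicate series of the comparisons. The deviations of same-numbered samples from their condition means correlated across genes at r = 0.691 for CO2-supplemented and 30 min, 0.372 for 30 and 60 min and 0.355 for 120 min and aerobic, and reached -0.234 for 30 and 120 min. Both a series term and a slide term (a separate dye effect for each of the 3 slides of 4 arrays) were fitted as alternatives. The others changed the background correction, the normalization within and between arrays, the summary and filter of probes, the dye term, the unit of replication, the arrays used, the values used and the variance prior, or left out 1 RNA sample. Leaving out 1 sample leaves its condition with a single RNA sample, which is then assumed to vary like the others. There were 29 alternatives in all.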

Results

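Relative transcript levels of 1810 genes were obtained for 10 RNA samples of L. johnsonii, 2 in each of 5 conditions. Cells grew under a condition labelled aerobic, or anaerobically with CO2 supplied (CO2-supplemented). Others were taken 30, 60 and 120 min after the CO2 supply was withdrawn from anaerobic, CO2-supplemented cultures. Median spot intensities of the 12 arrays lay between 1002 and 2111 units in Cy5 and between 1713 and 3537 in Cy3, with median local backgrounds of 611 to 827 and 741 to 975. In each array channel, 1550 to 1778 genes exceeded the foreign-gene control spots. The 2 samples of a condition differed with an SD across genes of 0.159 (log2) at 30 min, 0.161 at 60 min, 0.202 at 120 min and 0.185 under aerobic growth. The 2 CO2-supplemented samples, the control of most comparisons, differed with an SD of 0.336, and 205 genes differed between them by over 0.5. The median standard error of a change was 0.115 in every comparison, since all conditions share 1 estimate of spread. Errors and p-values may therefore be too small in comparisons against the CO2-supplemented pair, and too large in the others. The number of arrays limits the precision.

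**Figure D1:**
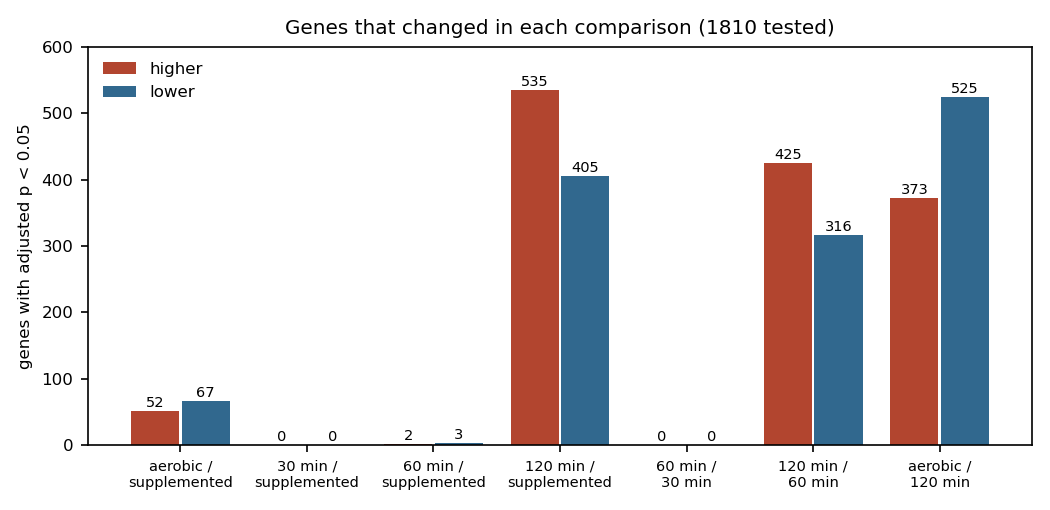
Number of genes with a limma adjusted p under 0.05 in each of 7 comparisons, higher or lower in the first-named condition, out of 1810 genes tested. The bars show 52 higher and 67 lower genes under aerobic growth, none at 30 min, 2 and 3 at 60 min, and 535 and 405 at 120 min.

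The first comparison asked how transcript levels differ between aerobic growth and anaerobic, CO2-supplemented growth. The condition labels do not say whether the aerobic cultures received CO2, so this comparison may mix oxygen with CO2 supply. Under aerobic growth LJ0081 was 3.05-fold lower (log2 change -1.61 ± 0.13, adjusted p 0.00063) and LJ0082 was 2.9-fold lower (-1.53 ± 0.10, adjusted p 0.000227). The 2 series gave -1.76 and -1.45 for LJ0081 and -1.56 and -1.51 for LJ0082, and all 15 and 16 probe positions had the same sign. LJ1254 rose 2.26-fold (1.18 ± 0.15, adjusted p 0.00944; 1.14 and 1.21 in the 2 series). These 3 genes passed under all 29 alternatives. The largest rises that passed were those of LJ1573 (1.65 ± 0.40, adjusted p 0.0484) and LJ1665 (1.54 ± 0.34, adjusted p 0.0382). Their changes differed between series, with 2.66 and 0.63 for LJ1573 and 2.31 and 0.77 for LJ1665, and 7 of the 10 probe positions of LJ1665 had a cross-hybridisation number above 1. LJ1573 lost its call under 13 alternatives and LJ1665 under 12; without CO2-supplemented sample 1 they stood at 0.95 and 0.98 (adjusted p 0.143 and 0.124). With slide as a block the LJ1573 log2 change, aerobic over CO2-supplemented, was 1.51 (adjusted p 0.138), and the LJ1665 log2 change, aerobic over CO2-supplemented, was 1.45 (adjusted p 0.103). Adjusted p-values over the alternatives ranged from 0.00123 to 0.23 and from 0.00126 to 0.199.

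In all, 119 genes passed, 52 that rose and 67 that fell, and 12 of them changed at least 2-fold. All 119 had the same sign in both series. Passing favours equal signs, because the spread between the 2 samples enters the test, so they are no separate support, here or below. An unadjusted p under 0.05 was reached by 618 genes. With slide as a block the count was 10, with the series as a replicate block 258, and with both 346. The slide block leaves the fit of the arrays no residual degrees of freedom, so lower counts with it, here and below, need not come from slides. Which direction held more genes depended on the setting: 47 rose and 101 fell with the authors' deposited ratios, whereas 196 rose and 150 fell with both blocks, 83 and 61 with dim probes left out, and 90 and 61 with near-background spots (code 2) left out. On the arrays that compared the 2 conditions directly, 1 on each of 2 slides and in opposite dyes, all 119 genes kept their sign. Direct arrays went into the fit that called the genes, so equal signs on them, here and below, are no separate support. The ratios of the 2 arrays correlated across genes at r = 0.595, with SDs of 0.493 for series 1 and 0.247 for series 2. Those 2 arrays gave 1.11 and 1.24 for LJ1254, -1.75 and -1.46 for LJ0081, and 2.44 and 0.85 for LJ1573. The count also changed when 1 sample of these conditions was left out. It rose without CO2-supplemented sample 2 and fell without CO2-supplemented sample 1 or either aerobic sample. It fell without samples of the time course as well, so such falls cannot be put down to the sample left out alone. Leaving out 1 sample of the time course, which takes no part in the change itself and lowers the degrees of freedom, gave 29 (30 min), 36 (60 min) and 48 (120 min), whichever sample it was. The count was 401 without the array of aerobic series 2 over CO2-supplemented series 2, on which 2727 spots carried quality code 1. That choice was made after the data were seen. Leaving out a CO2-supplemented sample, here and below, also takes the pair with the widest spread out of the shared estimate of spread. Counts without such a sample therefore do not show dependence on that sample alone.

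LJ0548 and LJ0549, reported whatever their p, did not pass under aerobic growth (0.44 ± 0.15, adjusted p 0.0894, and 0.27 ± 0.17, adjusted p 0.288). In series 1 their changes were 0.75 and 0.56, and in series 2 0.13 and -0.03. With both slide and series as blocks they were 0.71 (adjusted p 0.014) and 0.55 (adjusted p 0.0284), and without CO2-supplemented sample 2 the value of LJ0548 was 0.69 (adjusted p 0.00234). Adjusted p-values over the 29 alternatives ranged from 0.00234 to 0.43 for LJ0548 and from 0.0284 to 0.869 for LJ0549.

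**Figure D2:**
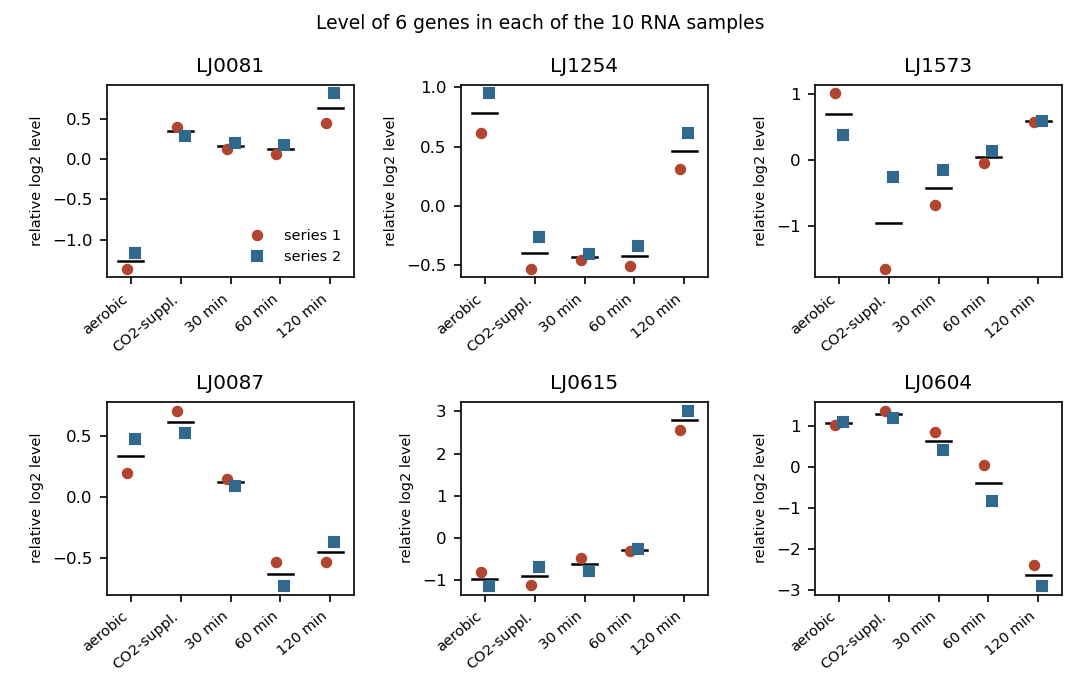
Relative log2 level (vertical axis, centred on the mean of the 10 RNA samples) of 6 genes in each condition (horizontal axis). Circles are series 1, squares series 2 and bars the mean of the 2. LJ0081 is lowest in the 2 aerobic samples (-1.36 and -1.17), LJ1573 has its 2 CO2-supplemented samples at -1.64 and -0.24, and LJ0615 is highest at 120 min (2.57 and 3.02).

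The time course asked which transcripts changed after the CO2 supply was withdrawn. No sample kept on CO2 was labelled as taken at the later times. In every comparison of the time course, time in culture therefore went along with CO2 withdrawal, and the design cannot separate them. At 30 min no gene passed in limma; 144 genes had an unadjusted p under 0.05, and the fit that took arrays as independent called 1. Values with the smallest unadjusted p were those of LJ0589 (0.58 ± 0.09, adjusted p 0.408) and LJ1122 (0.43 ± 0.09, adjusted p 0.592) upwards, and of LJ0087 (-0.50 ± 0.12, adjusted p 0.592) and LJ0085 (-0.38 ± 0.10, adjusted p 0.592) downwards, each with 1 sign in both series. The values of LJ0548, LJ0549 and LJ1254 were 0.34, 0.09 and -0.04, and none passed. Over the alternatives LJ0548 ran from 0.091 to 0.59. The count was also 0 with slide as a block, and it was 186 without CO2-supplemented sample 2. The direct arrays of the 2 series, each on a slide of its own, correlated across genes at r = 0.224 for this step.

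At 60 min 5 genes passed. LJ1122 rose 1.6-fold (0.68 ± 0.09, adjusted p 0.025) and LJ0589 rose 1.53-fold (0.62 ± 0.09, adjusted p 0.0496). LJ0087 fell 2.38-fold (-1.25 ± 0.12, adjusted p 0.00971; -1.25 and -1.26 in the 2 series), LJ0086 fell 1.98-fold (-0.99 ± 0.12, adjusted p 0.0187) and LJ0085, named because only 5 genes passed, fell 1.57-fold (-0.65 ± 0.10, adjusted p 0.0496). LJ0085, LJ0086 and LJ0087 have consecutive IDs. Of LJ0589, LJ1122 and LJ0085, 6 probe positions each had a cross-hybridisation number above 1. The values of LJ0548, LJ0549 and LJ1254 were 0.39, 0.42 and -0.03, and none passed. Their adjusted p-values were 0.181, 0.19 and 0.929. Over the alternatives LJ0548 ran from 0.14 to 0.64 and LJ0549 from 0.23 to 0.60.

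All 5 genes had the same sign in the sums of the direct arrays within each of the 2 slides. These gave -1.20 and -1.20 for LJ0087 and 0.83 and 0.52 for LJ1122, and correlated across genes at r = 0.259. Over the 29 alternatives LJ0087 lost its call under 2, LJ0086 under 8, LJ1122 under 13, LJ0085 under 15 and LJ0589 under 19. Values ran from -1.50 to -0.94 for LJ0087, -1.24 to -0.78 for LJ0086 and -1.09 to -0.39 for LJ0085. Those of LJ1122 ran from 0.30 to 1.26 and those of LJ0589 from 0.41 to 0.86. The count of 5, with 420 genes at an unadjusted p under 0.05, was 3 with slide as a block, 19 with the series as a replicate block and 24 with both. With arrays scaled to equal spread, 66 genes rose and 48 fell, and with the authors' deposited ratios 5 rose and 15 fell. The count also changed when 1 RNA sample was left out. It rose without CO2-supplemented sample 2 and fell without any other sample. Those others include the 30 min, 120 min and aerobic samples, which take no part in this comparison. Leaving out a sample lowers the degrees of freedom, so such falls do not show dependence on the sample left out alone.

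At 120 min 940 of 1810 genes (51.9%) passed. LJ0615 rose 13-fold (3.70 ± 0.20, adjusted p 3.62e-05; 3.68 and 3.71 in the 2 series) and LJ0201 rose 8.6-fold (3.10 ± 0.19, adjusted p 3.62e-05; 2.88 and 3.33). LJ0604 fell 15.4-fold (-3.94 ± 0.28, adjusted p 5.98e-05; -3.77 and -4.11) and LJ0605, the next ID, fell 7.61-fold (-2.93 ± 0.32, adjusted p 0.000219; -3.04 and -2.82). LJ1254 rose 1.82-fold (0.86 ± 0.15, adjusted p 0.00198; 0.84 and 0.88). These 5 genes passed under all 29 alternatives. LJ0548 (0.27 ± 0.15, adjusted p 0.158) and LJ0549 (0.11 ± 0.17, adjusted p 0.599) did not pass. Over the alternatives their values ran from 0.023 to 0.52 and from -0.14 to 0.30.

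Of the 940 genes, 535 rose and 405 fell, with a median size of 0.58, and 115 rose and 49 fell at least 2-fold. Each of the 940 had the same sign in both series, which passing favours. With slide as a block 530 genes passed, 280 that rose and 250 that fell, and with the series as a block too 428 rose and 441 fell, so the excess of rises depended on the setting. Without 120 min sample 2 the count was 583. The sums of the 3 direct arrays of each series, series 1 on 1 slide and series 2 on another, had the sign of the change for 922 of the 940 genes and correlated across genes at r = 0.613. They gave 3.99 and 3.34 for LJ0615, -3.50 and -4.36 for LJ0604, and 0.91 and 0.83 for LJ1254.

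**Figure D3:**
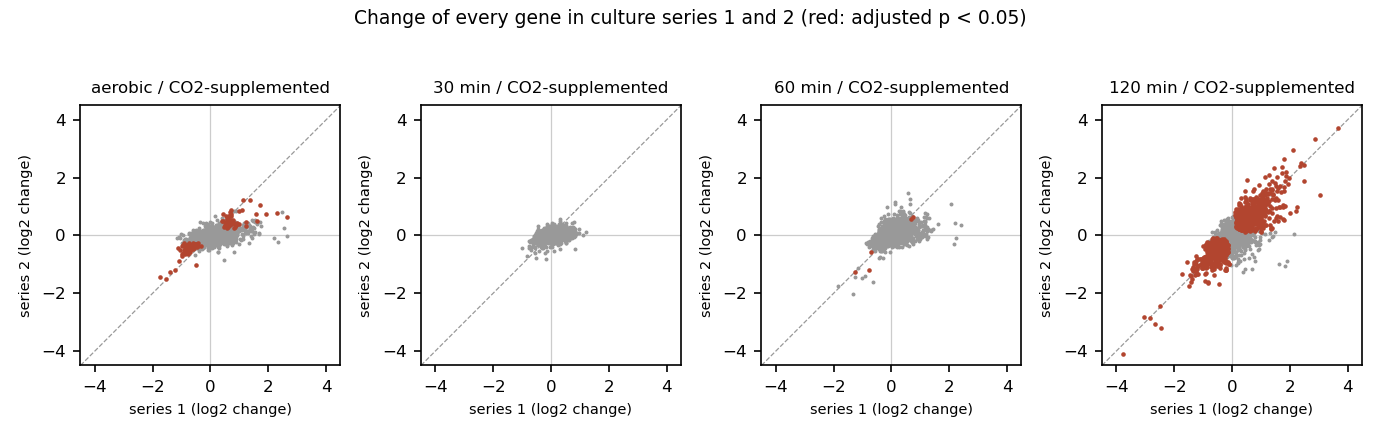
Log2 change of each gene in series 1 (horizontal axis) and series 2 (vertical axis) for 4 comparisons against the CO2-supplemented samples, with genes of adjusted p under 0.05 in red and the line of equal change dashed. Across genes the changes of the 2 series correlated at r = 0.609 (aerobic), 0.401 (30 min), 0.517 (60 min) and 0.782 (120 min); genes are not independent replicates.

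**Figure D4:**
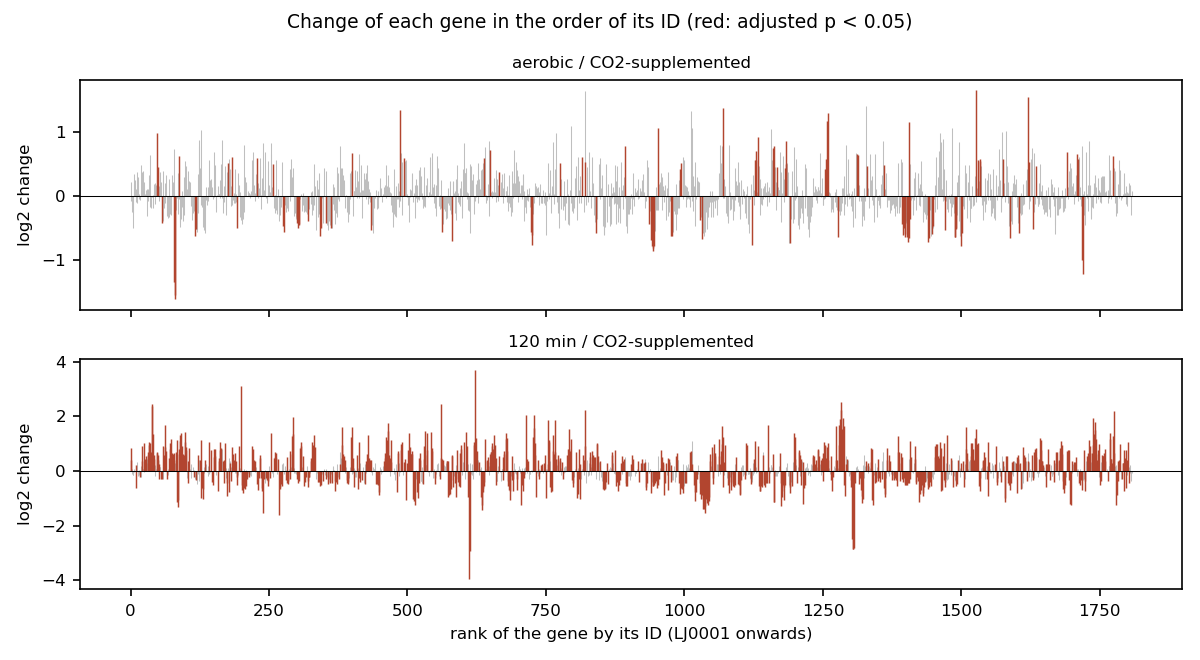
Log2 change of each gene (vertical axis) under aerobic growth and at 120 min against the CO2-supplemented samples, with genes in the order of their IDs (horizontal axis) and those of adjusted p under 0.05 in red. Across genes the changes of neighbouring IDs correlated at r = 0.405 (aerobic) and 0.538 (120 min).

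Between successive times, the median gene that passed at 120 min changed most in the last step, which lasted 60 min against 30 min for each of the others. From 60 to 120 min LJ0615 rose by a further 3.08 ± 0.20 (adjusted p 7.93e-05) and LJ0201 by 2.70 ± 0.19 (adjusted p 7.93e-05), and LJ0604 changed by -2.26 ± 0.28 (adjusted p 0.000787). LJ0605 changed by -1.13 ± 0.32 (adjusted p 0.0206), after -1.80 ± 0.32 up to 60 min, which did not pass (adjusted p 0.0711). LJ1254 changed by 0.89 ± 0.15 in this step (adjusted p 0.00239). LJ0087 gave 0.18 ± 0.12 (adjusted p 0.281), after -0.75 ± 0.12 from 30 to 60 min (adjusted p 0.232). In this last step 741 genes passed, 425 that rose and 316 that fell, while from 30 to 60 min none passed in limma, with 88 genes at an unadjusted p under 0.05 and 1 called with arrays taken as independent. Of the 940 genes that passed at 120 min, 223 (23.7%) had at least 50% of that change by 60 min, and the median share of it was 16.2% at 30 min and 22.5% at 60 min. Among the 164 that changed at least 2-fold, 16 had at least 50% by 60 min. These genes were chosen by their change at 120 min, which favours a large last step, and all shares use the same CO2-supplemented samples.

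All 741 genes of the last step had the same sign on the direct arrays of both series, which were part of the fit that called them. These arrays, on 2 slides, correlated across genes at r = 0.903. With slide as a block 348 genes passed. The count was 403 without 120 min sample 2, 474 without 60 min sample 1 and 487 without 60 min sample 2. An F-test over all 3 times against the CO2-supplemented samples passed 796 genes. With slide as a block it passed 330, and without 120 min sample 2 (genes changed over the CO2 depletion time course) 347. For the step from 30 to 60 min the count was 0 with slide as a block too, and the direct arrays correlated at r = 0.47.

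The last comparison asked whether the changes under aerobic growth and after 120 min of CO2 withdrawal differ; since both share a control, it is the contrast of aerobic growth with 120 min. LJ0081 and LJ0082 were lower under aerobic growth than at 120 min by -1.90 ± 0.13 (adjusted p 3.64e-05) and -1.75 ± 0.10 (adjusted p 2.42e-05). LJ0615 differed by -3.77 ± 0.20 (adjusted p 2.42e-05) and LJ0604 by 3.71 ± 0.28 (adjusted p 4.43e-05). For LJ1254, which rose in both, the difference of 0.32 ± 0.15 did not pass (adjusted p 0.118), and neither did that for LJ1573 (0.11 ± 0.40, adjusted p 0.834). In all, 898 genes differed, 373 higher and 525 lower under aerobic growth. With slide as a block 621 genes passed, 332 of them higher and 289 lower, and with the series as a block too 514 were higher and 465 lower. Only slide 1 held both conditions, joined through 4 arrays of series 1, and 885 of the 898 genes had the same sign there. Without 120 min sample 2, 565 genes passed.

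Both lists were set against each other. Of the 119 genes of the aerobic comparison, 64 also passed at 120 min, where independent lists of these sizes would share 61.8, so the total was near that of independent lists. Of the 64, 56 changed in the same direction and 8 in the opposite one. By direction, independent lists would share 15.4 genes that rose in both, where 21 did, and 15 that fell in both, where 35 did. They would share 11.6 that rose under aerobic growth and fell at 120 min, where 6 did, and 19.8 of the reverse, where 2 did. Unchanged groups simulated against the same 2 controls, without errors common to a series, shared 0.05 genes on average in 20 draws. With no gene changed, few could pass in these draws, so they give no reference for the overlap of the real lists. With 2 controls no split that leaves 2 on each side exists, so part of the overlap may come from the shared controls.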

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

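The simulation that kept the errors of a series together was chosen after the result was seen.

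The changes at 60 and at 120 min of CO2 withdrawal differed in 741 genes when the difference itself was tested, which is the step from 60 to 120 min in the report. Among them was LJ1254, 1 of the 3 IDs reported whatever their p: it changed by -0.03 up to 60 min and by 0.89 ± 0.15 from 60 to 120 min (adjusted p 0.00239), with the same sign in both series.

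Signal also appeared in spots that no comparison used. Of 61 control spot types that were neither genes nor foreign genes, 7 lay above the 95th percentile of the foreign-gene spots on every array in both dyes. Their median intensities were 711 to 967 in Cy5, where the percentile had a median of 609, and 983 to 1401 in Cy3, where it was 818. What these controls carry is not stated in the sources used here, and no explanation was tested.

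Changes under aerobic growth and at 120 min went together across genes (covariance 0.0588, r = 0.292), but both were taken against the same 2 CO2-supplemented samples, whose error enters both. In 1000 simulated data sets with this shared error and no change, the covariance averaged 0.0282 and reached at most 0.041, with a mean r of 0.699; when the errors of a series were also kept together, as deviations at 120 min and under aerobic growth correlated at r = 0.355, it averaged 0.0369, had the upper end of its central 95% at 0.0452 and reached the observed value in 1 draw. The observed 0.0588 lies above the central 95% in both simulations. The first drew the error of each gene independently, and errors shared between genes would widen such a range. Shared error as the whole cause therefore stays open. With a different CO2-supplemented sample as the control of each change, the covariances were 0.016 and 0.045 (r = 0.0582 and 0.293), against a highest simulated value of 0.015 without the series kept together, and with it 64 draws reached the lower one. That second test is open as well, and a part common to both responses may remain as a hypothesis, of a size that 2 control samples do not settle.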

How the results depend on the processing

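Of the 29 alternatives, 5 were chosen after the data were seen: probes of cross-hybridisation number 1 alone, spots of code 2 left out, all quality codes kept, spots on bright local background left out, and the array with the code 1 area left out.

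Of the comparisons of single genes named by ID, 577 kept their direction and side of the threshold under alternative processing, 33 lost and 5 gained a call, and 12 changed sign. When 1 RNA sample was left out, 258 kept both, 52 lost and 10 gained a call, and 10 changed sign. All sign changes were in values that passed neither as reported nor under the alternative. Counts stayed within 1.5 times the reported value in 121 cases under alternative processing, and lay above in 16 and below in 15. The median change over all genes moved by over 0.1 in 1 case, by -0.11 between aerobic growth and 120 min with the authors' ratios.

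The LJ0549 log2 change, 30 min, was -0.018 with slide as a block, -0.015 with arrays as independent and -0.018 with both blocks; leaving out 1 sample gave -0.096 to 0.28. The LJ0549 log2 change, 120 min, was -0.14 with slide as a block, -0.048 with arrays as independent, -0.14 with both blocks and -0.012 with spots on bright background left out; leaving out 1 sample gave -0.072 to 0.30. The LJ1254 log2 change, 60 min, was 0.017 without background subtraction and 0.022 with median centring, and -0.16 to 0.11 with 1 sample left out; the LJ1254 log2 change, 30 min, was then -0.17 to 0.094. The LJssrA log2 change, aerobic, was 0.027 with slide as a block, 0.027 with both blocks and 0.0020 without the array that had the code 1 area, and -0.46 to 0.15 with 1 sample left out; the LJssrA log2 change, 30 min, was then -0.43 to 0.18. In each of these ranges the lowest value is without CO2-supplemented sample 1 and the highest without sample 2.

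For the aerobic comparison (119 genes), 42 passed without background subtraction, 21 with arrays scaled to equal spread, 10 with slide as a block, 390 with arrays as independent, 258 with the replicate block, 346 with the replicate block and slide as a block, 49 with the loop arrays alone, 260 with the robust prior trend on intensity and 401 without the array that had the code 1 area. With 1 sample left out, the count ran from 4 (aerobic sample 1) to 697 (CO2-supplemented sample 2).

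At 60 min (5 genes) the counts were 0 without background subtraction, 18 with plain subtraction, 25 with median centring, 114 with arrays scaled to equal spread, 1 with the median over probes, 3 with slide as a block, 8 with arrays as independent, 19 with the replicate block, 24 with both blocks, 3 with the loop arrays alone, 20 with the authors' ratios, 33 with the robust prior trend and 3 with all quality codes kept. Leaving out 1 sample gave 0 (60 min sample 2) to 525 (CO2-supplemented sample 2). At 30 min 1 gene passed with arrays as independent, and leaving out 1 sample gave 0 to 186 (CO2-supplemented sample 2).

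At 120 min (940 genes) 530 passed with slide as a block, 485 of them shared with the 940, and 519 with arrays as independent; leaving out 1 sample gave 583 (120 min sample 2) to 1033. From 30 to 60 min 1 gene passed with arrays scaled to equal spread and 1 with arrays as independent. From 60 to 120 min (741 genes) 354 passed with equal spread and 348 with slide as a block, 343 of these shared; leaving out 1 sample gave 403 (120 min sample 2) to 891. Between aerobic growth and 120 min (898 genes) 396 passed with arrays as independent, and leaving out 1 sample gave 565 (120 min sample 2) to 1031. In the F-test (genes changed over the CO2 depletion time course, 796) the counts were 330 with slide as a block and 347 (120 min sample 2) to 1160 (CO2-supplemented sample 2) with 1 sample left out.

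Leaving out a sample lowers the degrees of freedom. Leaving out either CO2-supplemented sample nevertheless raised the counts for the last step of the time course and for aerobic growth against 120 min. Neither contrast uses those samples, so these rises came from the estimate of spread that all conditions share. How far this explains the larger counts without CO2-supplemented sample 2 in the other comparisons was not tested. Beyond that, the cause of changed counts was not tested. Not tested were 196 genes with dim probes left out, 321 with spots of code 2 left out, 101 with number 1 probes alone and 3 with spots on bright background left out. Set tests of gene lists were not run, since no ID matched a name. Signal limits dim genes: on the channels of a condition, 32 (120 min) to 154 (aerobic) genes exceeded the foreign-gene level on none.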

Other observations

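Tests chosen after the result was seen were those of a dye effect as the whole cause, of 1 share in every gene, of the step from 30 to 60 min and of aerobic growth minus 60 min, and LJssrA was chosen after its values were seen.

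The 2 CO2-supplemented samples differed more (SD 0.336) than the pairs of the other conditions. A fault on a single array is argued against, since 2 estimates of the difference from disjoint arrays correlated across genes at r = 0.743. The difference went with the fitted dye effect at r = -0.353, but its SD was 0.339 on the 2 arrays where a constant dye effect cancels. A constant dye effect may thus be part of the cause and not the whole. These 2 arrays lay on different slides, and a dye effect that differs between slides was not tested as the cause. A culture further along the last step of the response is argued against by r = 0.0407 with the change from 60 to 120 min.

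The difference, taken as series 2 minus series 1, went with aerobic growth minus 30 min at r = 0.595 and with 60 min minus 30 min at r = 0.519, where data simulated without a link gave -0.154 to 0.0550 and -0.163 to 0.124. On disjoint arrays the values were lower, 0.466 for aerobic growth minus 30 min, and 0.449 (series 1) and 0.284 (series 2) for 60 min minus 30 min, the last under the bound of 0.3 set for that step. Some oxygen in the CO2-supplemented culture of series 2, and a start on the step from 30 to 60 min, both stay open, and these contrasts share the 30 min samples. With aerobic growth minus 60 min instead, r was 0.251 (simulated, -0.190 to 0.113), between the bounds set for and against oxygen. Oxygen therefore cannot be told apart from what the 30 min samples bring in. The draws for aerobic growth minus 30 min took the error of each gene independently. Errors shared between genes would widen such ranges, so values outside them do not exclude shared error.

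A mixture with 1 aerobic share in every gene could not be settled. Shares were taken as log2 differences over the change from 30 min to aerobic growth. On this scale and baseline, 1 true share need not give equal values in genes that rise and genes that fall. In the 11 genes at least 2-fold higher under aerobic growth than at 30 min the median share was 1.11, and in the 4 genes at least 2-fold lower it was 0.0503, with all 11 and all 4 shares above 0. LJ0081 and LJ0082, low under aerobic growth, differed by -0.12 and -0.03 between the 2 samples, and LJ1254, high under it, by 0.26. Such a mixture, a response of some genes alone, or another difference between the cultures stays open.

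Genes with consecutive IDs changed together. At 120 min the changes of neighbours correlated at r = 0.538, with a permutation p of 1e-05, the smallest that the shuffles can give, and 557 of the 939 called genes with numbered IDs lay in 124 runs of at least 3 genes called in the same direction. In shuffled order at most 224 did. With probes of cross-hybridisation number 1 alone the correlation was 0.51, against 0.523 for the same 1708 genes with all probes. Probes with a higher number thus did not account for most of it. The meaning of the number is not stated, so cross-hybridisation between neighbours stays open. Spots of consecutive genes lay 1.00 times as far apart on the slide as random pairs, which argues against closeness on the slide. Transcription of neighbouring genes together stays open and was not tested, as no gene positions were at hand.

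LJssrA carries the symbol of transfer-messenger RNA in its ID. It gave 0.93 ± 0.24 at 60 min (adjusted p 0.115; 1.21 and 0.64 in the 2 series) and 0.78 ± 0.24 at 120 min (adjusted p 0.024; 1.35 and 0.21). Over the 29 alternatives the 120 min value ran from 0.47 to 1.09 and passed in 26. Under aerobic growth and at 30 min it did not pass (-0.16, adjusted p 0.673, and -0.13, adjusted p 0.867).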
